A study of Mus musculus with 4 samples.

How the data were processed

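Whole retinas of adult mice were profiled on 4 microarrays, 2 per genotype. Per the labels, the knockout mice carried floxed alleles of Nrl on both chromosomes and the control mice on a single chromosome, so the controls kept an intact allele. All mice carried CAG-CreERTM, a Cre recombinase that acts after tamoxifen binds it, and all received 4-hydroxytamoxifen by daily intraperitoneal injection on postnatal days 42 to 44. Retinas were collected on postnatal day 63. Each array held total RNA pooled from 4 retinas of 2 animals, extracted with TRIzol LS and RNeasy columns and amplified to biotinylated cDNA with a NuGEN Pico kit, per the labels' protocols.

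The authors deposited log2 values for 21897 probe sets on each of the 4 arrays. The submitters' processing notes name affy and limma, with no version and no role. The background correction and the normalization are not given in the sources used here. The values ran from 1.34 to 12.75, and the array medians were 6.00 and 6.04 for the knockout pools and 5.99 and 6.03 for the control pools, so the arrays lay on a common scale, which was kept. The log2 scale was taken from this range, since no source states it. No detection values were used, and a low level cannot be told from background. The number of arrays limits the precision of every value.

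Probe sets were named through the platform annotation. It gave 20877 probe sets 1 gene symbol, 175 several and 845 none. Symbols were checked through the gene ID against RefSeq names of the GRCm38.p6 assembly, where 36 IDs were not matched and 0 symbols were changed. Probe sets with several symbols or none entered no gene-level test. For the 778 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene, which left 19421 genes. No filter on low signal was applied.

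Knockout and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 19421 genes) with genotype as the only term. A gene was called at an adjusted p under 0.05. Fold changes are knockout minus control on the log2 scale, and SE is the moderated standard error. The replicates are pools of different animals, so the p-values measure the spread between pools, not between single animals. An exact permutation test cannot pass 0.05 here, since 4 arrays split into 2 and 2 in only 3 ways and the smallest p it allows is 1 in 3.

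The samples' grouping, the design, the alternatives, the naming rule and 25 gene lists were fixed before the data were examined. The rule named Nrl first, then the 10 called genes with the largest change in each direction whose knockout arrays lay all above or all below the controls. It added up to 4 called members of each list, or the 2 members with the smallest p in a list with no call, and a set of photoreceptor, glial and sex-linked genes whatever their p. Genes named outside the rule were chosen after their values were seen, and this is said beside them. The lists held 322 genes, of which 292 were measured. The other 30 were not analysed here.

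The lists covered rod and cone phototransduction, other rod-enriched and cone-enriched genes, photoreceptor transcription factors, outer segment and visual cycle, photoreceptor synapse, bipolar, amacrine, horizontal and ganglion cells, and Müller glia identity. They also covered reactive gliosis, microglia and macrophages, complement and antigen presentation, interferon response, cell death, unfolded protein response, glycolysis, immediate early genes and vascular cells. Carry-over of retinal pigment epithelium, lens and erythrocytes, and sex-linked genes, made up the rest. The 24 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, again with an estimated correlation, and with fry, whose p as given here tests whether a list's genes move one way on balance. With an estimated correlation, camera works on the residual degrees of freedom of the 4 arrays, so it has little power here. Benjamini-Hochberg adjustment ran over the 24 lists. Members were also counted after adjustment over the list alone.

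The same steps were tested on simulated data for this comparison, with 19421 genes, in 20 simulations. In each, 200 genes were changed, and a list of 12 other genes was shifted by 0.5 and also counted as changed. They called 0.299% of genes changed by 0.5 on the log2 scale, 42.2% of those changed by 1 and 80.3% of those changed by 2, and 1.09% of calls were false. Lists of 12 genes shifted by 0.5 passed an unadjusted camera p under 0.05 in 20 of 20 simulations, and lists that were not shifted in 0. Simulated genes varied independently, so these values do not show how often camera errs where genes of a list vary together. Their variances were drawn from those measured on few arrays, which scatter more widely than true variances. The shares of genes called and of false calls may therefore differ in the real data.

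Alternatives were the replicate number as a block, leaving out each array, quantile normalization, median centring, leaving out genes under the 30th or 50th percentile of mean signal, the mean of a gene's probe sets, every probe set on its own, a variance trend, a robust variance and array weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.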

Results

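Expression was measured in whole mouse retina after loss of Nrl in the adult animal. Nrl is the leucine zipper transcription factor that specifies rod photoreceptors, and its absence from early development turns rods into cone-like cells. The comparison asks which genes differ when the gene is removed from a mature retina, 19 days after the last injection of 4-hydroxytamoxifen. There were 2 arrays of knockout retinas and 2 of control retinas, each a pool from 2 animals. Across probe sets, Pearson's r between arrays ran from 0.987 to 0.990, and probe sets are not independent replicates.

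Nrl itself had a log2 level of 7.57 and 7.05 in the knockout pools and 8.21 and 8.13 in the control pools. Its knockout mean was 7.31 ± 0.37 (SD, n = 2) against 8.17 ± 0.05 (SD, n = 2) in control, a log2 fold change of −0.86 (SE 0.18), or 55.2% of the control signal. Both knockout pools lay below both control pools, in the direction of the labels, but the difference did not pass the correction over all genes (limma adjusted p = 0.289). The control mice carried a floxed allele too, and where the probes of Nrl lie relative to the deleted part is not given in the sources used here. The level of this probe set is therefore a limited check of the deletion.

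Gnat1, the α subunit of rod transducin, fell furthest of the called genes. It dropped from 12.61 ± 0.05 to 9.61 ± 0.21 (SD, n = 2 each), a log2 fold change of −3.01 (SE 0.13, limma adjusted p = 0.00586) that left 12.4% of the control signal. Its levels of 12.65 and 12.58 were the highest on the control arrays, and whether signal is compressed there was not tested. Gnb1, the β subunit of transducin in rods, fell by 1.47 (SE 0.12, adjusted p = 0.0208) to 36.1%. In the opposite direction, the cone transducin subunits Gnb3 and Gnat2 rose 3.02-fold and 2.14-fold, and so did A2m and Stat3, genes of reactive glia, and Ctss and Tyrobp, genes of microglia, by 2.71-fold, 2.11-fold, 2.89-fold and 2.17-fold.

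Of 19421 genes, 39 were called, 27 higher and 12 lower in the knockout, and 35 of them changed at least 2-fold (24 higher, 11 lower). At an unadjusted p under 0.05 there were 1374 genes. The replicate number followed the sex of the pools. The spread within each group, on which the p-values of the 39 calls rest, thus includes any difference between the sexes. Xist, the RNA of the inactive X chromosome, had levels of 4.07 and 4.09 in replicate 1 of knockout and control and of 10.66 and 10.47 in replicate 2, and the Y-linked Kdm5d, Uty and Eif2s3y ran the other way, while the Y-linked Sry, at 7.03 and 7.13 in the knockout pools and no higher than 7.20 in control, did not follow this pattern; Eif2s3y and Sry were chosen after their values were seen. With the replicate number as a block, 8 of the 39 genes and no others were called, each at an adjusted p of 0.0429: Gnat1, Reep6, Glb1l2, Clca1, Ccdc175, Lrrc2, Tceanc2 and Ifitm3. The block leaves fewer residual degrees of freedom, and 1607 genes had an unadjusted p under 0.05 with it. Without knockout replicate 1 there were 7 calls (3 higher, 4 lower), without knockout replicate 2 there were 11 (5 higher, 6 lower), and without either control replicate limma called 0 (1355 and 1328 genes at an unadjusted p under 0.05).

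Several of the called genes that fell most encode proteins of rod photoreceptors. Reep6, a membrane trafficking protein of rods, fell by 1.99 (SE 0.11, adjusted p = 0.00825) to 25.2% of control, with differences of −2.09 in replicate 1 and −1.89 in replicate 2. Rom1, a disc rim protein, fell by 1.24 (SE 0.10, adjusted p = 0.0209), with −1.27 and −1.22 in the separate replicates. The remaining called genes with the largest falls were not on any list. The galactosidase-like genes Glb1l3 and Glb1l2 fell by 2.44 and 1.80, and hybridisation shared between these relatives was not tested, so their separate sizes are uncertain. Ebpl, a relative of the emopamil binding protein, fell by 1.47, Rabgef1, an exchange factor for Rab5, by 1.36, and Tdrd7, a Tudor domain protein, by 1.04. Ccdc180 fell by 1.58 at the probe set used, but 8 of its 27 probe sets were lower at an unadjusted p under 0.05, and the mean of its probe sets, −0.31, was not called (adjusted p = 0.602). Both replicate differences were negative in each of these genes, which follows from the naming rule.

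Among the 10 called genes that rose most, Clca1, of the family of chloride channel accessory proteins, led with a log2 fold change of 2.11 (SE 0.11, adjusted p = 0.00825). Its differences in replicates 1 and 2 were 2.11 and 2.12. Ccdc175 rose by 1.93 (SE 0.12) and Lrrc2 by 1.64 (SE 0.10), both at an adjusted p of 0.00825. Ifitm3, an interferon-induced membrane protein, rose by 1.90 (SE 0.19, adjusted p = 0.0366), and S100a6, a calcium-binding protein, by 1.83 (SE 0.14, adjusted p = 0.0208). Tmem26 rose by 1.67 and Prtg, an immunoglobulin superfamily member, by 1.54. Ctss, the lysosomal protease cathepsin S, rose by 1.53 and Gnb3 by 1.59. Tceanc2 rose by 1.74 at the probe set used, while its other probe set stood at −0.01 and their mean, 0.87, was not called (adjusted p = 0.0844).

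The rod phototransduction list ranked lower than other genes as a whole. Of its 12 measured genes, 2 fell (Gnat1 and Gnb1), 0 rose and 10 did not pass over all genes, while 9 were lower when adjusted over the list alone. The list's median log2 fold change was −0.47, and its mean difference was −0.71 in replicate 1 and −0.72 in replicate 2. Camera gave an adjusted p of 2.87e-16, the adjusted p was 0.146 with an estimated correlation, and fry gave 0.00492. Pde6b, the β subunit of rod phosphodiesterase, had −0.82 (SE 0.10, adjusted p = 0.0644). Cngb1, of the rod cyclic nucleotide-gated channel, and Gngt1, the rod transducin γ subunit, were chosen after their values were seen, at −0.76 and 0.05. Of 4 Cngb1 probe sets, 3 lay between −0.76 and −0.48 and the last at −0.05.

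**Figure D1:**
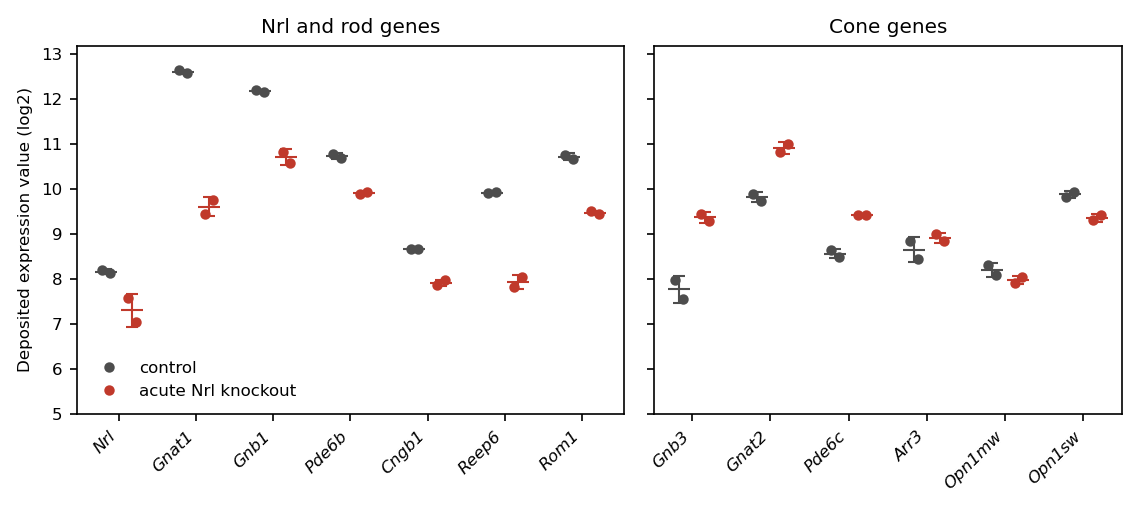
Log2 expression level on each array for Nrl and rod genes (left) and cone genes (right), control in grey and knockout in red. Points are arrays and bars give the mean ± SD of 2 pools; Gnat1 dropped from 12.61 to 9.61 on average, while Gnb3 rose from 7.78 to 9.37 and Opn1sw had means of 9.89 and 9.36.

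Other rod-enriched genes also ranked low. Of 11 measured, 2 fell (Reep6 and Rom1), 0 rose and 9 did not pass, and 5 were lower when adjusted over the list alone. The median was −0.29, and camera gave an adjusted p of 1.71e-09 (adjusted p = 0.146 with an estimated correlation, fry 0.0217). The outer segment and visual cycle list shares Rom1 and Rp1 with the other rod-enriched genes, and Rp1, chosen after its value was seen, had −0.73 (adjusted p = 0.148). This list had 22 measured genes, of which 2 fell, Rom1 and the photoreceptor retinol dehydrogenase Rdh12, at −1.01 (SE 0.11, adjusted p = 0.0410). Adjusted over the list alone, 8 of its members were lower and 3 higher. Among those chosen after their values were seen, Abca4, the outer segment retinoid transporter, had −0.67 and Prph2, a partner of Rom1 at the disc rim, −0.61, against 0.49 for Impg2, a proteoglycan of the matrix around photoreceptors. The median of this list was −0.15, with a camera adjusted p of 2.10e-04 (adjusted p = 0.188 with an estimated correlation, fry 0.0217).

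In the cone phototransduction list 2 genes rose, and both encode transducin subunits. Gnb3, the β subunit of cone transducin, rose by 1.59 (SE 0.16, adjusted p = 0.0366), and Gnat2, its α subunit, by 1.10 (SE 0.12, adjusted p = 0.0402). The rises in replicates 1 and 2 were 1.47 and 1.72 for Gnb3 and 0.93 and 1.27 for Gnat2. Pde6c, the catalytic subunit of cone phosphodiesterase, had 0.87 (SE 0.10), just short of the threshold (adjusted p = 0.0616). The opsin genes did not pass. The S opsin gene Opn1sw had −0.52 (SE 0.11, adjusted p = 0.281), with −0.52 in each replicate, the M opsin gene Opn1mw had −0.22 (SE 0.12, adjusted p = 0.793), and the cone arrestin gene Arr3 had 0.26 (SE 0.16, adjusted p = 0.819). Of the 11 measured members Gnb3 and Gnat2 rose, 0 fell and 9 did not pass, and 3 were higher and 1 lower when adjusted over the list alone.

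As a whole, the cone phototransduction list was not called by camera (adjusted p = 0.258, and adjusted p = 0.686 with an estimated correlation). Its median, −0.13, lay below 0 while its mean, 0.22, and the direction of camera lay above. Fry gave an adjusted p of 0.345. The camera call appeared without knockout replicate 2 (adjusted p = 0.0447) and without control replicate 1 (adjusted p = 0.0382). The mean change of the cone list exceeded that of the rod list by 0.93 on the log2 scale, with cone minus rod list means of −1.22 and −1.31 on the knockout arrays and −2.10 and −2.30 on the control arrays. A two-sided exact permutation test of these values gave p = 0.333, the smallest it can give with 2 arrays against 2.

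Of 8 other cone-enriched genes none was called at an adjusted p under 0.05, and 1 was higher and 2 lower when adjusted over the list alone. Fabp7, a fatty acid binding protein that glia also make, had 1.27 (SE 0.22, adjusted p = 0.202), and Kcne2, a potassium channel subunit, had −0.46 (SE 0.10, adjusted p = 0.289). The mean of this list was 0.08, while its median, −0.07, and camera's direction were below 0 (adjusted p = 0.600). Among 12 photoreceptor transcription factors none was called, and 1 was higher and 2 lower when adjusted over the list alone. Crx, which acts in rods and cones, had −0.20 (SE 0.10, adjusted p = 0.777), the cone factor Thrb −0.16 (SE 0.11, adjusted p = 0.850) and Esrrb −0.57 (SE 0.14, adjusted p = 0.421). Camera gave this list an adjusted p of 0.296. Nr2e3 was not analysed here. The photoreceptor synapse list, with 13 genes, had 0 calls and a camera adjusted p of 0.739, with Cabp4, a calcium sensor of the photoreceptor terminal, at −0.44 and Ctbp2, which encodes the ribbon protein RIBEYE, at 0.20.

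Genes of reactive gliosis and neurotrophic stress ranked highest. All 19 measured members lay above 0, with a median of 0.70 and mean differences of 0.70 in replicate 1 and 0.83 in replicate 2. Over all genes 4 rose, 0 fell and 15 did not pass, and 16 were higher when adjusted over the list alone. The 4 were A2m, the protease inhibitor α2-macroglobulin, by 1.44 (SE 0.10, adjusted p = 0.0176), Cebpd, a transcription factor of the acute phase response, by 1.40 (SE 0.15, adjusted p = 0.0402), Osmr, the receptor of oncostatin M, by 1.30 (SE 0.12, adjusted p = 0.0294), and Stat3, which carries cytokine signals to the nucleus, by 1.08 (SE 0.10, adjusted p = 0.0271). Camera gave an adjusted p of 9.43e-27, with an adjusted p of 0.146 with an estimated correlation and 0.0302 from fry. Gfap, the intermediate filament of reactive glia, had 0.70 (SE 0.15, adjusted p = 0.317). Fgf2, a growth factor, had 1.64 (adjusted p = 0.102) and was chosen after its value was seen.

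Müller glia identity genes had 0 calls among 13, with 2 higher when adjusted over the list alone. These were Clu, which encodes clusterin, at 0.89 (SE 0.10, adjusted p = 0.0583) and Crym at 0.80 (SE 0.11, adjusted p = 0.0965). The median was 0.10, with 10 genes above 0 and 3 below. Among the latter, Glul had −0.37 (adjusted p = 0.518) and Rlbp1 −0.32 (adjusted p = 0.783), both chosen after their values were seen. Camera gave an adjusted p of 0.0658 (adjusted p = 0.397 with an estimated correlation and 0.116 with the replicate block, fry 0.0978). The list passed after quantile normalization (0.0415), without genes under the 50th percentile of mean signal (0.0429) and with a variance trend (0.0269). Without knockout replicate 2 the list mean was 0.16, against 0.13 over all arrays.

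In the microglia and macrophage list, 2 of 17 measured genes rose, Ctss by 1.53 (SE 0.15, adjusted p = 0.0327) and Tyrobp, a signalling adaptor of myeloid cells, by 1.12 (SE 0.11, adjusted p = 0.0347), 0 fell and 15 did not pass. Adjusted over the list alone, 9 were higher and 1 lower. The lower gene, Tmem119, a marker of resident microglia, had −0.40 (adjusted p = 0.403), and Aif1, which encodes Iba1, had 0.96 (adjusted p = 0.0912); both were chosen after their values were seen. In the list 13 genes lay above 0 and 4 below, with a median of 0.38, and the mean differences were 0.41 in replicate 1 and 0.42 in replicate 2. Camera gave an adjusted p of 6.76e-09, with an adjusted p of 0.146 with an estimated correlation and 0.0314 from fry.

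In the complement and antigen presentation list, 0 of 11 genes were called over all genes and 5 were higher when adjusted over the list alone. Serping1, the C1 inhibitor, had 0.99 (SE 0.13, adjusted p = 0.0901) and B2m, the light chain of class I molecules, 1.48 (SE 0.22, adjusted p = 0.122). Camera placed the list higher (median 0.14, adjusted p = 5.73e-05, adjusted p = 0.188 with an estimated correlation, fry 0.126). Of 13 interferon response genes 1 rose, Ifitm3, and 12 did not pass, with 3 higher when adjusted over the list alone. Its median was 0.14 and camera gave an adjusted p of 9.06e-04 (adjusted p = 0.209 with an estimated correlation, fry 0.0978). The microglial markers given above, median 0.38, moved in the same direction as these lists.

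**Figure D2:**
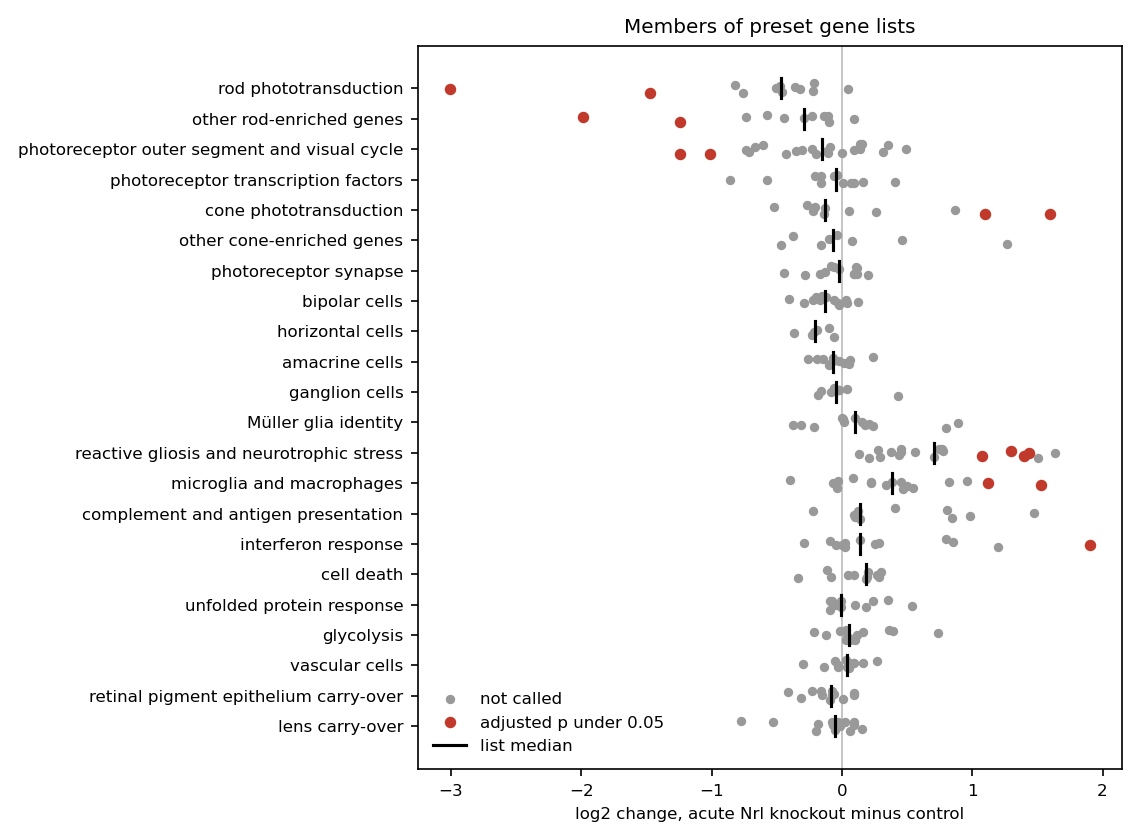
Log2 fold change (knockout minus control) of every measured member of 22 gene lists. Each point is a gene, red where its adjusted p was under 0.05, and black bars mark list medians, from −0.47 for rod phototransduction to 0.70 for reactive gliosis.

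No member of the horizontal, bipolar, amacrine or ganglion cell lists was called. All 6 horizontal cell genes lay below 0, with a median of −0.20, and Calb1, the calcium-binding protein calbindin, had −0.37 (SE 0.10, adjusted p = 0.475). Camera placed this list lower (adjusted p = 0.00538, adjusted p = 0.304 with an estimated correlation, fry 0.0760), and without knockout replicate 1 its adjusted p was 0.0584. The 14 bipolar genes had a median of −0.13 and a camera adjusted p of 0.0232 (adjusted p = 0.631 with an estimated correlation, fry 0.492), with Tacr3, the neurokinin 3 receptor, at −0.41 (SE 0.10, adjusted p = 0.399). That call was lost without knockout replicate 2 (adjusted p = 0.475), without control replicate 1 (adjusted p = 0.532) and without genes under the 50th percentile of mean signal (adjusted p = 0.0998). The amacrine list (12 genes, camera adjusted p = 0.258) and the ganglion cell list (10 genes, camera adjusted p = 0.600) were not called. Gad1, which makes GABA, had −0.26, and Pou4f3, a ganglion cell transcription factor, had 0.43 (adjusted p = 0.483).

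Among metabolic and stress lists, glycolysis ranked higher by camera (15 genes, median 0.06, adjusted p = 0.0336, adjusted p = 0.512 with an estimated correlation, fry 0.310) with 0 members called and 1 higher when adjusted over the list alone. That gene was Hk2, a hexokinase of photoreceptors, at 0.74 (SE 0.14, adjusted p = 0.240). The glycolysis call was lost with the replicate block (adjusted p = 0.0564), without knockout replicate 1 (0.234) and without control replicate 2 (0.342). The 11 cell death genes had a median of 0.18 and no call, and camera gave an adjusted p of 0.155. Gadd45a, a DNA damage response gene, had −0.33. The 11 unfolded protein response genes had a median of −0.01 against a mean of 0.10 and a camera direction above 0 (adjusted p = 0.143), and Atf3, a stress-induced transcription factor, had 0.54 (adjusted p = 0.358) and was higher when adjusted over the list alone. This list passed without knockout replicate 1 (adjusted p = 0.0422) and without genes under the 50th percentile of mean signal (0.0318). The 11 immediate early genes were not called (camera adjusted p = 0.426), with the heat shock gene Hspa1a at −0.37.

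Lists of tissues that could come along with a dissected retina held no called gene. Retinal pigment epithelium genes had a median of −0.08 (12 genes, camera adjusted p = 0.155), with Rpe65, the visual cycle isomerase, at 7.31 in control replicate 1 against 6.37 to 6.72 in the other pools. Without control replicate 2 this list was called lower (adjusted p = 2.48e-04). Lens genes had a median of −0.05 (16 genes, camera adjusted p = 0.172), 1 of them, the crystallin gene Crygd, was lower when adjusted over the list alone, at −0.77 (adjusted p = 0.297), and the list was called lower without control replicate 1 (adjusted p = 0.0382). Vascular genes (12 genes, camera adjusted p = 0.739) were not called. Only 2 erythrocyte genes were measured, so that list was not tested, and Alas2, of haem synthesis in erythroid cells, had −0.12. The 4 measured sex-linked genes were not called between genotypes (camera adjusted p = 0.950).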

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

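The alternatives were chosen before the data were examined. No result that was called in the comparison of all arrays turned in direction under any of them. In all 39 called genes the arrays of the 2 groups lay apart, so leaving out an array could not turn these genes. Results that were not called turned for 4 genes and 6 lists when an array was left out: Xist (log2 fold change −3.21 to 3.38), Kdm5d (−2.09 to 1.49), Uty (−2.38 to 2.56) and Slc4a1 (−0.16 to 0.11), and the lists of ganglion cells (adjusted p 0.319 to 0.921), photoreceptor synapse (0.353 to 0.976), photoreceptor transcription factors (0.0655 to 0.839), pigment epithelium (2.48e-04 to 0.532), vascular cells (0.230 to 0.835) and sex-linked genes (0.302 to 0.465). The sex-linked list also turned under median centring (0.935). For Xist, Kdm5d and Uty the group that keeps 1 array then holds pools of 1 sex, and for the others the cause was not tested. With the replicate number as a block, a pairing that the labels do not explain, limma called 8 genes in place of 39 (5 higher, 3 lower, all 8 at least 2-fold), and these 8 were among the 39. The block leaves fewer residual degrees of freedom, and genes at an unadjusted p under 0.05 rose from 1374 to 1607. The fall in calls alone is therefore no measure of the genotype differences. Differences between replicates 1 and 2 correlated across genes at 0.239 between the genotypes, or 0.142 without Xist and Y-linked genes. The block also ended the call of the glycolysis list and changed no other list call. The lone pool that remains when an array is left out was assumed to vary like the other group. Leaving out each array in turn gave 0 to 11 calls, 0 to 5 higher, 0 to 6 lower and 0 to 11 with at least a 2-fold change. The share of higher calls, 69.2% over all arrays, was 42.9% without knockout replicate 1 and 45.5% without knockout replicate 2, and fewer samples entered those fits. The cone phototransduction list then had an adjusted p from 0.0382 to 0.976, and the excess of the cone over the rod list mean ran from 0.83 to 1.03. A variance trend called 128 genes (81 higher, 47 lower, all 39 among them), and the cause was not tested. Leaving out genes under the 30th percentile of mean signal gave 68 (49 higher, 19 lower) and under the 50th percentile 89 (58 higher, 31 lower), where fewer genes were tested. With every probe set tested, 26 probe sets were called, 15 of them higher, with more tests to adjust for. The share higher was 57.7% of called probe sets against 69.2% of called genes. Quantile normalization (46 calls, 38 shared), median centring (53, all 39 shared), the mean of probe sets (36 shared of 36), robust variance (38 of 38) and array weights (39 of 39) stayed within 1.5 times the count. Nrl was never called, with an adjusted p from 0.0748 to 0.705. With an estimated correlation between genes the rod phototransduction, reactive gliosis and microglia lists each had an adjusted p of 0.146, and of the lists other than rod and cone phototransduction 0 were called in place of 9. In that setting camera also works on the few residual degrees of freedom of 4 arrays, which by itself raises its p. How far the correlation between genes contributed was not tested. The pseudocount alternative was not run, since the deposited values are on a log scale already. Signal over background cannot be judged for dim probe sets without detection values.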

Other observations

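The calls between genotypes and the mean over probe sets were planned, while the tests of genes near Nrl, of rod and cone cell numbers and of other splits of the arrays were chosen after the results were seen. Of the 39 called genes, 12 have not been described, and they were picked here because their values passed. Cerkl, a gene mutated in inherited retinal dystrophy, rose by 1.31, and Agtpbp1, which removes glutamate side chains from tubulin, by 1.15 from an already high level of 10.22. Transcription factors among them were Sox30 at 1.45, the E2F family repressor E2f6 at 1.27, and the Notch target Hey2 at 1.13. Nupr1, a stress-induced nuclear protein, rose by 1.11, Tnnt2, the cardiac form of troponin T, by 1.21, and Cryzl2 by 1.17. Myo10, an unconventional myosin of filopodia, rose by 0.97, Akr1b8, an aldo-keto reductase, by 0.96, and Cd47, the surface protein that restrains phagocytosis, by 0.88. Sh2d1a, an adaptor known from lymphocytes, fell by 0.99.

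Among the called genes, Glb1l2 lies next to Glb1l3, and Ccdc180 next to Tdrd7, in the gene order of GRCm38.p6. Shared hybridisation between the first pair was not tested, and the mean of the Ccdc180 probe sets was not called (adjusted p = 0.602). In Ccdc180, 7 of its 27 probe sets had changes from −1.58 to −0.63 while the other 20 lay between −0.28 and 0.28. A probe set with no gene symbol, 10400742, had −1.55 (adjusted p = 0.0472 over all probe sets). Of the 30 measured genes nearest to Nrl, 2 passed an unadjusted limma p of 0.05 where 2.12 would by the share over all genes. They were Ipo4 at 0.47 (unadjusted p = 0.00248) and Jph4 at 0.26, named after their values were seen. Of the 30 genes 0 were called, and their median change was 0.06. The genes near Nrl thus held no excess of changed genes. With 2 arrays per group and a floxed allele in the controls too, an effect of sequence around that allele on single genes cannot be excluded.

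Nrl signal stood at 55.2% of control and Gnat1 signal at 12.4%, a difference in log2 change of −2.15 (SE 0.22). How much background lies under the Nrl signal is open, and so is any compression of the Gnat1 signal, the highest on both control arrays. No explanation of this difference was tested.

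Log2 changes of the 12 rod phototransduction genes ran from −3.01 for Gnat1 to 0.05 for Gngt1, and 2 of the 12 were called. Fewer rod cells could lower them all alike, but the SD of the 12 changes was 7.68 times their root mean square standard error, or 3.65 times without the lowest and the highest gene. This argues against loss of rods as the whole cause where probe sets respond alike and the genes are made only in rods. How far other cells of the retina make them was not tested. A partial loss of rods beside a separate fall of Gnat1 and Gnb1 stays open. The 95% interval lay below 0 for 9 of 12 genes, the exceptions, named after their values were seen, being Pde6a, Rcvrn and Gngt1, and such a loss cannot be told apart from smaller changes per cell in whole retina. No biological explanation per cell was tested.

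Log2 changes of the 11 cone phototransduction genes ran from −0.52 for Opn1sw to 1.59 for Gnb3, with 2 called higher and 0 lower. More cone cells alone could raise them all alike, but the SD of the 11 changes was 4.47 times their root mean square standard error, or 3.29 times without the lowest and the highest gene. Fewer cones alone could not raise any, and 3 genes, Gnb3, Gnat2 and Pde6c, lay above 0 by more than 2 standard errors. Both values argue against a change in the number of cones as the whole cause where probe sets respond alike and the genes are made only in cones. How far other cells of the retina make these genes was not tested. Opn1sw and Cngb3, the latter named after its value was seen, lay below 0 by more than 2 standard errors. Cngb3, at −0.27 (SE 0.13), did not reach an unadjusted p under 0.05 (limma unadjusted p = 0.081), so its fall is uncertain. No biological explanation per cell was tested here either.

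The 4 arrays split into 2 and 2 in 3 ways, and 1 of these, the real one, called as many as 39 genes. The highest of the other splits, by replicate number, called 4 (Xist, Kdm5d, Uty and Eif2s3y), and 3 splits are too few for a share under 0.05. In the other splits each group held 1 knockout and 1 control array. Genotype differences then added to the spread within groups, so few calls there are no measure of how many the real split would call without a genotype effect.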
